A study of Drosophila melanogaster with 2 samples.

How the data were processed

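Chromatin immunoprecipitation followed by sequencing was carried out on 2 samples of 0 to 24 hour Drosophila embryos, which form 1 group and are numbered 2 and 3 as biological replicates, per the labels. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels' protocols. Each list was derived from the alignments and a further data set that also served to make control-normalised tracks, per the deposited readme files. That control was not analysed here, so no background level of this line or antibody is set beside the values. The sources used here do not give the aligner, the peak caller, the IDR threshold or the number of reads. Depth is therefore unknown, and no interval that needs it is given.

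The authors deposited peak lists in narrowPeak format on dm6 and on dm3, each replicate with a relaxed list from its own alignments, a pooled relaxed list from both, and the IDR list from these, per the deposited readme files. The relaxed lists are named there as peaks together with background for input to IDR, and the longest held 30000 entries. The deposited signal value of a peak is a score of the authors' caller with no stated scale, used here to rank peaks within a list. The deposited -log10 q value reached its maximum of 3.69 for 2452 of the 3203 IDR peaks and so ranked them poorly. The IDR list was tested against the pooled list in both builds, and its rows were exactly the strongest of the pooled list by signal value. Its signal values are thus pooled values with no error of their own, and taking as many of the strongest pooled peaks gives the same set. The peaks had nearly fixed widths, with medians of 430 bp in replicate 2, 370 bp in replicate 3 and 404 bp in the pooled and IDR lists. A nearly fixed width means that overlap depends on the distance between summits more than on the extent of binding.

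The dm6 lists were the main data. Chromosome sequences came from the Release 6 assembly, and every dm6 peak lay within its 6 arms. Gene models came from Ensembl release 115 (BDGP6.54), with 13945 protein-coding genes on these arms. Positions on dm3 were never converted, and dm3 lists were only compared with each other.

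The grouping of samples, the tests, the gene lists and the motifs were fixed before the data were examined. The overlap of the replicates was taken over the 3203 strongest peaks of each, because lists of the same length are needed for ranks to compare. Summits were classed in the order promoter (within 500 bp of a TSS of a protein-coding gene), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. The expected shares came from 10000 random positions in each of 100 draws, with the arms in the proportions of the peaks, and p from 100000 multinomial draws of as many summits with those shares. Gene lists were compared with 10000 random lists in 10 bins of window length (two-sided, called a permutation test, smallest p 0.0002), and a gene with several peaks counted once. Motif shares were compared by an exact McNemar test on peaks that had a match in only one of the paired windows. Differences between promoter and other peaks were tested by permuting the class over the peaks. P-values were adjusted by the Benjamini-Hochberg method within each family (7 classes, 6 arms, 18 lists, 10 motifs), with a threshold of 0.05. These tests run over peaks or genes of 1 group, so their p-values describe this peak set and not the spread between embryos. Wilson intervals treat peaks or genes as independent and cover counting error only.

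The genes named were set by rule: the nearest protein-coding gene by TSS of each of the 15 strongest IDR peaks, the 10 genes with the most IDR summits in the body or within 5 kb, up to 4 members of each list with the strongest peak and up to 4 without a peak, and slp1 and slp2. One gene that this rule takes is not reported here. Genes named as the neighbour whose promoter holds such a peak follow from it. Of 559 list symbols, 2 had no protein-coding match. Dl and nos were matched to Delta and nanos, their present symbols, after the lists had first been run. A further 2 symbols were repeats within a list, and 16 genes stand in more than 1 list.

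Alternatives changed one choice at a time: the overlap rule, the number of peaks, the build, the promoter and gene windows, the matching, the motif window and its flank, the strength of the peaks and the replicate used. Rearranged letters of the stricter forkhead form were tested after its other values were seen. In addition, 4 alternatives were chosen after seeing the data: random lists matched also on the number of other TSSs in the window, a gene's own TSS within 500 bp, flank windows matched in A and T content from 600 to 3000 bp away, and IDR peaks held by the strongest set of both replicates.

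The procedures were tested on simulated data. For the replicate comparison, of 3203 simulated peaks 50.0% were planted as shared and 50.8% were found shared. For the gene lists, over 13945 genes, 2.2% of unplanted lists had an unadjusted p under 0.05, and 95% of lists with peaks planted at 10 of 20 genes were called. For the motif comparison, over 1900 windows, a motif planted in 20.3% gave an excess of 18.8%. The simulated summits and flanks had the same base frequencies, so this could not show an excess that comes from base composition. The simulated lists used randomly drawn genes over randomly placed background peaks. They could not show the effect of peaks gathered at promoters or of neighbouring genes in a list. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.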

Results

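Binding of the forkhead transcription factor Sloppy paired 2 (Slp2) was mapped by chromatin immunoprecipitation and sequencing in whole Drosophila melanogaster embryos collected from 0 to 24 hours after egg laying, with both sexes together. The embryos came from a transgenic line that carries Slp2 fused at its C terminus to green fluorescent protein, and the chromatin was precipitated with an antibody against that protein. The series holds 1 group of 2 samples, numbered as biological replicates 2 and 3, and no second condition, so the comparisons below are between the replicates, between bound and randomly chosen positions or genes, and between summits and their flanks. The authors deposited a list of peaks for each replicate, a list called on both replicates together, and a list thresholded by the irreproducible discovery rate (IDR), a procedure that compares the ranks of peaks between replicates. The IDR list holds exactly the strongest peaks of the pooled list, and some of its members rank far apart in the replicates. On the dm6 genome these lists held 30000, 30000, 28637 and 3203 peaks. The number of reads behind them is not recorded in the peak lists, so the depth of each sample is unknown. Each peak's signal value is the authors' score and is used here mainly to rank peaks within a list, beside a few ratios and a correlation of log2 values. All coordinates are dm6.

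The 15 strongest IDR peaks lay mostly at promoters. Of these, 10 had their summit within 500 bp of a transcription start site (TSS), 4 lay in introns and 1 was intergenic. The strongest had its summit at 19590620 on arm 3L (peak 19590439 to 19590811), 96 bp from the TSS of CG14100, with a signal value of 1453.32, which was 14.2 times the median of the list. The peak ranked next lay at 481081 on arm 2L (peak 480887 to 481297, signal 1345.67), inside an intron of ush, which encodes the GATA cofactor U-shaped, and 1393 bp from the TSS of cbt. It was followed by a promoter peak 40 bp from Ugalt, a UDP-galactose transporter gene (X, summit 2703892, signal 1304.05), and by one 197 bp from px (2R, summit 22514296, signal 1206.9). Promoter peaks at Chro, which encodes a chromatin protein, ph-p, which encodes a Polycomb group protein, CG1888, mRpL41, Art3, PNPase and Pal1, and intronic peaks at CG11050, Lk6 and CG32772, completed the group together with an intergenic peak 11938 bp from CG13323. All 15 ranked 23 or better in replicate 2 and 27 or better in replicate 3, which follows in large part from their choice by the signal of both replicates together.

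The genes with the highest numbers of peaks included some of great length. CG1677 on X (7281089 to 7405797) had 15 IDR summits in its body or within 5 kb of it, of which 2 had one of its own TSSs as the nearest. The ush gene had 13 and kirre, which encodes a myoblast adhesion protein, also had 13, over windows of 74341 and 404149 bp, or 0.175 and 0.0322 peaks per kb, where the X arm that holds kirre had 25.6 per Mb. An own TSS was the nearest for 9 of the peaks at ush and 5 of those at kirre. The count was 11 for Raf, which encodes the kinase downstream of Ras, and for tara. It was 10 each for CHES-1-like, itself a forkhead gene, for the nuclear receptor gene Hr4 and for sbb, and 9 each for CG14434 and Ptp61F, of which 4 and 1 had an own TSS as the nearest. Of the 15 peaks at CG1677, 14 overlapped the 3203 strongest peaks of replicate 2 and 14 those of replicate 3, and the corresponding numbers for the 13 at ush were 12 and 11.

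How far the replicates agreed was asked of their 3203 strongest peaks each. In replicate 2, 2317 of them (72.3%, 95% Wilson interval 70.8 to 73.9) overlapped one of replicate 3 by at least 1 bp, against a mean of 1.78% and a maximum of 2.72% after 1000 circular shifts of one list along each arm (one-sided permutation p = 0.001, the smallest these shifts can give). Of the IDR peaks, 84.1% overlapped the strongest set of replicate 2, 85.0% that of replicate 3 and 71.0% both, which follows in large part from the list's choice by the pooled signal. Across the 3148 IDR peaks with a summit within 200 bp in both samples, Spearman's rho of the signal values was 0.583 (95% bootstrap interval 0.555 to 0.609) and Pearson's r of their log2 values was 0.665. Peaks are not independent replicates, so no p is given. These peaks were chosen by the signal of both replicates together, so rho describes the chosen set and not the agreement over all peaks. The log2 ratio of the 2 replicates' signal values had a standard deviation of 0.68. The circular shifts do not keep peaks at promoters, so their p shows only more overlap than random placement gives. It cannot set sites of Slp2 apart from places precipitated with many factors.

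**Figure D1:**
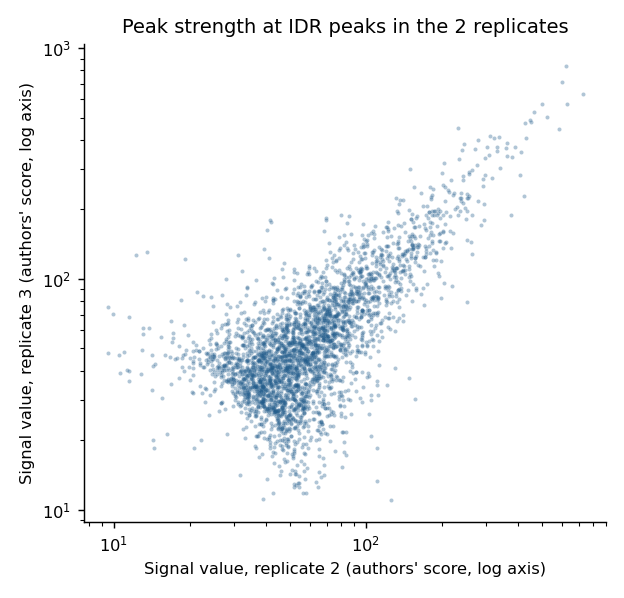
Each point is an IDR peak with a summit in both replicates (3148 peaks), placed by the authors' signal value in replicate 2 (x axis) and replicate 3 (y axis), both log axes. Spearman's rho is 0.583 over all of them and 0.581 in the stronger 50% of the IDR peaks.

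IDR summits fell at promoters far more often than randomly chosen positions did. Of the 3203 summits, 1631 (50.9%, 95% Wilson interval 49.2 to 52.7) lay within 500 bp of a TSS of a protein-coding gene, against 11.5% of random positions on the same arms, a 4.42-fold excess. Introns outside promoters held 1048 summits (32.7% against 39.9%) and intergenic sequence 426 (13.3% against 27.7%). Coding exons held only 6 (0.187% against 13.9%) and 3' UTRs 26 (0.812% against 4.56%). Each of these 5 differences had a p of 2e-05, the smallest that 100000 multinomial draws from the shares of random positions can give (two-sided, adjusted p = 2.8e-05 over 7 classes, n = 3203 summits). For the 16 summits in 5' UTRs (adjusted p = 0.068, n = 3203) and the 50 in other exons (adjusted p = 0.983) the difference from random positions did not pass the threshold of 0.05. Because the class shares sum to a fixed total, the promoter excess by itself lowers the shares of the other classes. Their falls were not tested apart from it, so the lower share of introns does not show that introns were avoided. The median distance from a summit to the nearest TSS was 468 bp, and 274 summits (8.55%) lay more than 10000 bp away. By arm, chromosome 4 held fewer peaks than its length predicts, 14 or 0.434 of the number expected (exact binomial test, adjusted p = 0.00305 over 6 arms). No other arm passed the threshold, with X at 1.07 of its expected number (exact binomial test, adjusted p = 0.222).

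**Figure D2:**
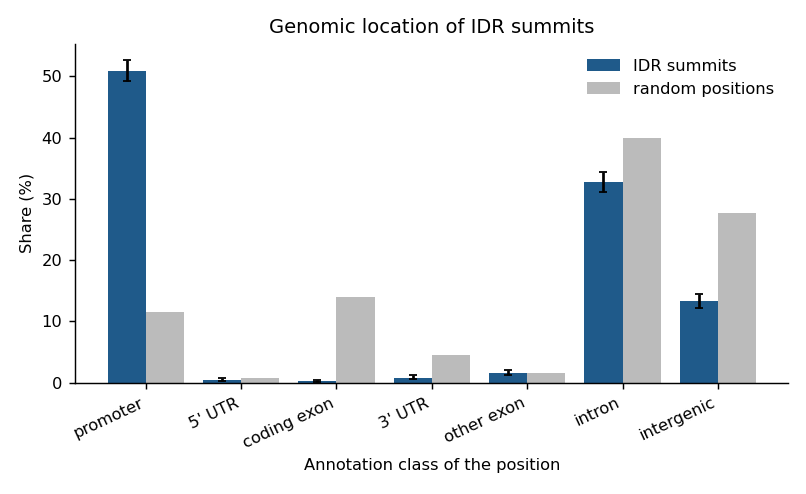
Bars give the share in percent of the 3203 IDR summits (blue, with 95% Wilson intervals) and of random positions on the same arms (grey) in each annotation class. Promoters hold 50.9% of summits and 11.5% of random positions, and coding exons 0.187% and 13.9%.

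Whether Slp2 peaks gathered at genes of particular kinds was tested for 18 gene lists. A gene counted as having a peak when an IDR summit lay in its body or within 5 kb, as it did for 5500 of 13945 protein-coding genes (39.4%), and each list was set against 10000 random lists matched on window length. With adjustment over the 18 lists, 3 lists had more genes with a peak than matched lists, 3 had fewer and 12 did not pass the threshold of 0.05.

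The genes for cytosolic ribosomal proteins stood furthest above their matched lists. A peak was found at 71 of 85 (83.5%, 95% Wilson interval 74.2 to 89.9), against a mean of 28.8 in matched lists (2.47-fold, two-sided permutation test, adjusted p = 0.0012). In 64 of them a summit lay within 500 bp of the gene's own TSS, 6.25 times the mean of matched lists. RpS27 on 3R (25245955 to 25247514) had a summit 5 bp from its TSS with signal 520.613 (rank 45; ranks 89 and 33 in replicates 2 and 3), and RpL7 on 2L (10201004 to 10202321) had one at 26 bp with signal 448.724 (rank 71). For RpS7 the strongest peak of the window, with signal 344.448, lay at the promoter of a neighbour, CG9743. RpL10Aa, RpL15, RpL21 and RpL40 were among the 14 genes of the list with no IDR peak. At the 68 promoter peaks of this list the site of the promoter factor DREF stood at 26.5% of summits and 1.47% of flanks (exact McNemar test, adjusted p = 0.000763 over 10 motifs), and the forkhead consensus at 32.4% and 39.7% (adjusted exact p = 0.784).

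Genes of the Notch pathway and the Enhancer of split complex had a peak at 15 of 20 (1.86-fold, adjusted permutation p = 0.0117). The strongest, at the promoter of the corepressor gene gro (3R, summit 26042519, signal 387.746), was counted for gro and also for E(spl)m7-HLH and E(spl)m8-HLH, whose windows overlap it. An intronic peak inside mam, which encodes a Notch coactivator, had a signal of 309.421, with the TSS of CG18371 the nearest at 4112 bp. Delta, Ser, Su(H) and H had no IDR peak. The call for this list was kept in 8 of 12 alternative settings. The ratio was 2.23 with lists matched also on the number of other TSSs (adjusted permutation p = 0.0009). In the stronger 50% of the peaks it was 2.94 (adjusted permutation p = 0.0012). With neighbours that share a peak counted once, 9 of 14 genes had a peak (1.43-fold) and the difference no longer passed (adjusted permutation p = 0.506). It also missed the threshold with windows of 20 kb (1.36-fold, adjusted permutation p = 0.112) and, at ratios above that of the list as tested, with peaks given to the nearest TSS alone (2.18-fold, adjusted permutation p = 0.0545) and with own promoters (2.11-fold, adjusted permutation p = 0.244).

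Genes of Dpp and EGFR signalling had a peak at 17 of 22 (1.54-fold, adjusted permutation p = 0.0414). Mad, which encodes a Smad protein of the Dpp pathway, had an intronic summit (2L, 3153418, signal 390.077). The spi gene, which encodes the EGFR ligand Spitz, had a promoter summit 175 bp from its TSS (2L, 19575762, signal 373.206). The strongest peaks in the windows of gbb (signal 565.772) and Med (signal 460.064) lay at the promoters of eIF6 and Mnat9. Among members with no IDR peak were put, scw, tld and rho. The call for this list ended in 6 of the 12 alternative settings, though the ratio hardly moved in 3 of these. It was 1.51-fold with the ranking of replicate 3 alone (adjusted permutation p = 0.066) and 1.53-fold with 20 bins of window length. It was 1.55-fold with genes that share a peak left out, a rule that removed no gene of this list (17 of 22). The call there changed only through redrawn random lists and the adjustment over the lists. With peaks at the gene's own promoter the ratio was 0.672. The call was kept in 6 settings. Among these, the ratio was 1.74 with lists matched also on the number of other TSSs (adjusted permutation p = 0.00792). It was 2.15 in the stronger 50% of the peaks (adjusted permutation p = 0.0054). With peaks given to the nearest TSS alone it was 2.31 (adjusted permutation p = 0.0072).

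The lists with fewer genes than matched lists were odorant and gustatory receptors, cuticle proteins and blood and fat body markers. Receptor genes had a peak at 19 of 119 (0.438 of the mean of matched lists, adjusted permutation p = 0.0012) and cuticle protein genes at 8 of 70 (0.343 of it, adjusted permutation p = 0.0012). Some members of both lists lie side by side, such as Gr10a and Gr10b on X, which had no peak. The random lists were drawn gene by gene, so neighbours without a peak counted separately and these p-values may be too small. None of the genes in either list had a summit within 500 bp of its own TSS. The strongest peak counted for a receptor gene, Gr61a (signal 268.328), lay at the promoter of CG13901, and the strongest for a cuticle protein gene, Cpr78Cc (signal 474.195), at that of CG11309. The next for cuticle proteins was an intergenic peak (signal 217.807) 1598 bp from the TSS of Cpr76Ba, which was also counted for Cpr76Bb and Cpr76Bc. Of the blood and fat body markers, 2 of 19 had a peak, Lsp2 and Hml (0.242 of the mean of matched lists, adjusted permutation p = 0.0173). The peak counted for Lsp2, a larval serum protein gene, lay 48 bp from the TSS of yps. The call for this list ended in 5 of the 12 alternative settings, one of them the ranking of replicate 3 alone (ratio 0.473, adjusted permutation p = 0.152). In the others the ratio was 0.724 with windows of 20 kb, 0.39 in the stronger 50% of the peaks, 0.297 with the nearest TSS alone and 0 with own promoters. The call for cuticle proteins ended with windows of 20 kb (ratio 0.783, adjusted permutation p = 0.112) and in the stronger 50% of the peaks (ratio 0.498, adjusted permutation p = 0.122).

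The lists closest to the known developmental role of Slp2 did not pass the threshold against matched lists. Some of these lists are small, so a moderate difference could be missed. The central 95% of matched lists had 1 to 7 genes with a peak for the pair-rule list and 3 to 10 for the gap and maternal list. Of the 9 pair-rule segmentation genes, 2 had a peak (adjusted permutation p = 0.598): slp1 and slp2 themselves, with none at eve, ftz, run or hairy, which the annotation lists as hry. This count moved both ways with the settings. It was 0 of 9 with a TSS within 2 kb or with own promoters, 0 of 7 without members of other lists and 1 of 9 in the stronger 50% of the peaks, none past the threshold. It was 4 of 9 with the ranking of replicate 2 alone (1.11-fold, adjusted permutation p = 1), 8 of 9 with windows of 20 kb (1.23-fold, adjusted permutation p = 0.804) and 6 of 9 with peaks given to the gene of the nearest TSS (2.43-fold, adjusted permutation p = 0.0675). The gap and maternal patterning genes had 4 of 14 (adjusted permutation p = 0.598), with a promoter summit 227 bp from bcd (signal 125.071) and none at hb, Kr, kni or knrl. Genes of segment polarity and Wnt and Hedgehog signalling had 11 of 24 (adjusted permutation p = 0.929), including intronic peaks inside fz (signal 309.592) and nkd (signal 162.508). The strongest in the window of pan, on chromosome 4, lay 38 bp from the TSS of RpS3A (signal 158.609). The list had none at en, hh, ci or gsb. Hox genes and Polycomb targets had 6 of 12 (adjusted permutation p = 1), Antp the strongest with an intronic summit of signal 117.376. Neuroblast factors had 6 of 24, 0.541 of the mean of matched lists (adjusted permutation p = 0.131), led by a peak in the window of nerfin-1 (signal 136.935). With a summit within 2 kb of a TSS required, these last groups passed as lower (adjusted permutation p = 0.0499 for each). Hox genes had 0 of 12 and neuroblast factors 2 of 24. With windows of 5 kb and lists matched also on the number of other TSSs, none of the lists in this paragraph passed. The ratios were then 0.757 for neuroblast factors (adjusted permutation p = 0.81), 0.929 for pair-rule genes and 0.933 for gap and maternal genes. For segment polarity and Hox genes they were 1.10 and 1.26. That matching was not run with the 2 kb windows.

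Of the remaining lists, mesoderm and muscle regulators had a peak at 14 of 24 (adjusted permutation p = 0.646). The strongest of these, signal 754.94, lay in the window of Mef2, a muscle differentiation gene, at the promoter of Pal1. The forkhead family, which includes slp1 and slp2, had 9 of 17 (adjusted permutation p = 0.785), with intronic summits at CHES-1-like (signal 286.054) and jumu (signal 150.63) and a promoter summit at fkh (signal 184.529). The fkh peak was uneven between the samples, ranking 210 in replicate 2 and 2400 in replicate 3. Terminal neuronal genes had 10 of 20 (adjusted permutation p = 1), with a promoter summit 254 bp from elav (signal 312.369). Head and eye determination genes had 6 of 17 (adjusted permutation p = 0.598), and passed as lower with the ranking of replicate 2 alone (3 of 17, adjusted permutation p = 0.0458). Ectoderm, trachea and gut regulators had 12 of 21 (adjusted permutation p = 0.929). With peaks given to the gene of the nearest TSS alone, that list and the forkhead family passed as higher, with 13 of 21 (2.10-fold, adjusted permutation p = 0.0108) and 10 of 17 (2.56-fold, adjusted permutation p = 0.009). Germline and testis genes had 10 of 21 (adjusted permutation p = 0.785), the strongest peaks of bgcn and bam lying at the promoters of eIF6 and RpS27. Heat shock genes had 9 of 17 (adjusted permutation p = 0.598), led by a summit 169 bp from the TSS of Hsp27 (3L, 9383894, signal 299.279).

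**Figure D3:**
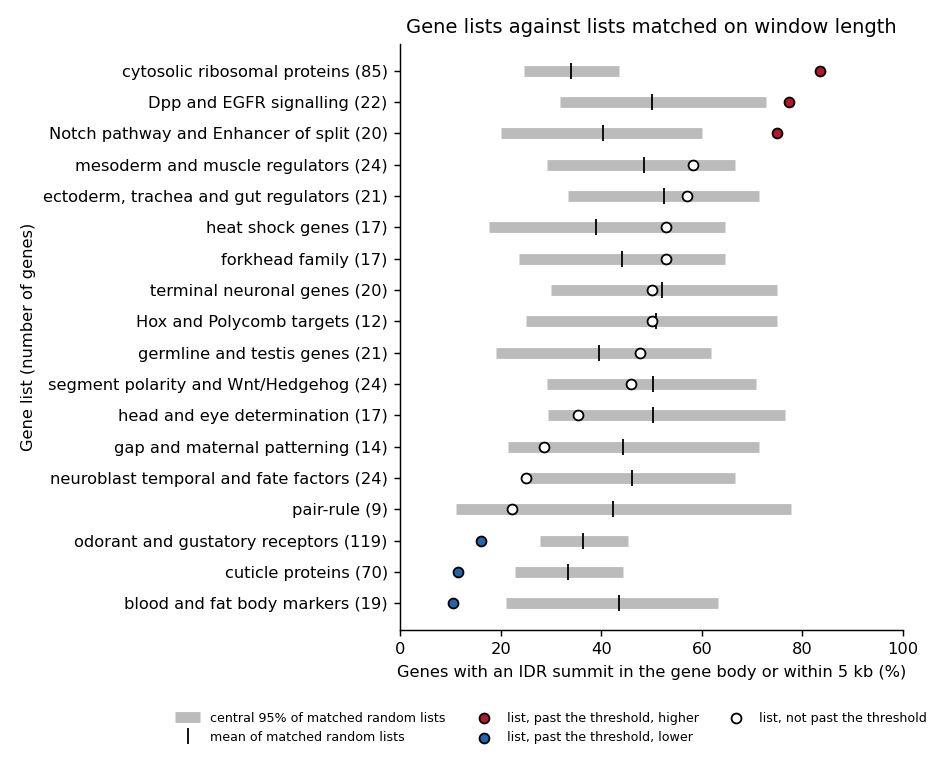
Each point is the percent of a list's genes with an IDR summit in the gene body or within 5 kb (red above and blue below the matched lists past the threshold, white not past it), the grey bar is the central 95% of 10000 random lists matched on window length and the tick their mean. Cytosolic ribosomal proteins reach 83.5% and cuticle proteins 11.4%.

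At the locus of the tagged gene, 8 IDR summits lay in the region from 20 kb before slp1 (2L, 3825675 to 3827099) to 20 kb after slp2 (2L, 3836840 to 3839185). The strongest was intergenic, between the paired genes, with its summit at 3832526 (peak 3832369 to 3832641), 4314 bp before slp2. Its signal of 511.667 ranked 47 in the IDR list, 60 in replicate 2 and 47 in replicate 3, and its window held a forkhead match. The other 7 had signals of 66.8 to 93.2. One of them lay 782 bp past slp1 (summit 3827881, signal 89.6161) and ranked 1131 in replicate 2 and 4891 in replicate 3. No IDR summit lay within 500 bp of the TSS of slp1 or slp2. The region also held 31 peaks of the pooled relaxed list, more than 98.7% of windows of its length. The labels do not state whether the tagged slp2 is an extra genomic copy, which would raise reads there.

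**Figure D4:**
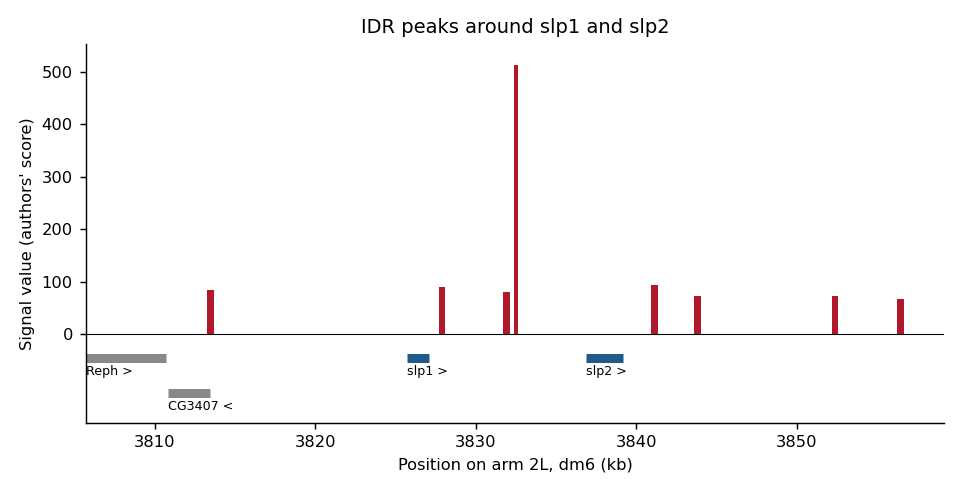
Bars mark the 8 IDR peaks on arm 2L (x axis in kb, dm6), each as wide as the peak and as high as the authors' signal value (y axis), over the protein-coding genes of the region (blue slp1 and slp2, grey others, arrowheads for strand). The peak between slp1 and slp2 reaches 511.667 and the other 7 stay between 66.8 and 93.2.

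Slp2 belongs to the forkhead family, whose members bind the consensus RYAAAYA (R is A or G, Y is C or T), so the 200 bp around each summit were searched for it and for 9 other motifs, and compared with the window 1000 bp to the higher-coordinate side. A forkhead match was present at 51.8% of summits and 41.4% of flanks, a difference of 10.4 ± 1.25 percentage points (SE, 3203 peaks, exact McNemar test, adjusted p = 1.17e-15). The stricter form GTAAACA was present at 7.15% and 4.71%, a difference of 2.44 points (adjusted exact p = 9.48e-05). That difference was 1.44 points with the ranking of replicate 3 alone (adjusted exact p = 0.0356), and the call ended in the stronger 50% of the peaks (1.81 points, adjusted exact p = 0.0876) and at distal peaks (1.34 points, adjusted exact p = 0.238). At promoter peaks the excess of RYAAAYA was 15.1 points and at the others 5.53 (permutation test of the difference, adjusted p = 0.001). The summit shares were close, 51.2% and 52.5%, and the gap came from the flanks, at 36.1% and 46.9%. Rearranged consensus letters reached as large an excess in 50 and 64 of 104 cases. The summits were also richer in A and T, 62.9% against 57.0% in the flanks. Against flank windows matched in that content the difference for RYAAAYA was 0.0312 percentage points (adjusted exact p = 1), and 56 of the 104 distinct rearrangements of its letters had an excess as large. For GTAAACA the difference from matched flanks was 1.72 points (adjusted exact p = 0.0125), and 3 of 209 rearrangements had an excess as large. No change of the RYAAAYA difference with peak strength was detected. It was 9.67 ± 2.79 points (SE) in the strongest 641 peaks and 11.7 ± 2.80 in the weakest 640 (Spearman's rho -0.0097, bootstrap interval -0.045 to 0.024, permutation p = 0.582).

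The clearest motifs were those of promoter factors. TATCGATA, the site of DREF, a regulator of replication and growth genes, was present at 4.03% of summits and 0.812% of flanks (4.96-fold, adjusted exact p = 1.30e-16), and none of the 591 rearrangements of its letters had an excess as large. GGTCACAC, the site of the core promoter factor M1BP, was present at 2.37% and 0.718% (3.30-fold, adjusted exact p = 9.73e-08). Both excesses were at promoter peaks. There DREF matches stood at 7.60% of summits against 0.674% of flanks, while at the 1572 other peaks they stood at 0.318% against 0.954%, and the promoter and other peaks differed in this excess by 7.56 percentage points (permutation test, adjusted p = 0.0005, from the smallest p these permutations can give). The flank of a promoter peak is centred 1000 bp from its summit, and promoters without a peak were not compared. Whether DREF and M1BP sites exceed those at promoters in general was therefore not tested. The Runt site was less frequent at summits, 3.78% against 5.46% (adjusted exact p = 0.00323). Homeodomain sites (adjusted exact p = 0.0567), Zelda sites (adjusted exact p = 0.413), GAGA factor sites (adjusted exact p = 0.514), Grainyhead sites (adjusted exact p = 0.622) and Twist E-boxes (adjusted exact p = 0.809) did not pass the threshold. Homeodomain sites passed as higher in 7 of 11 alternative settings, but their difference was -1.72 points against flanks matched in A and T content (adjusted exact p = 0.0903) and -1.02 points at distal peaks (adjusted exact p = 0.61). The Runt call ended in 4 of 11, and the M1BP call ended in the stronger 50% of the peaks (adjusted exact p = 0.0553).

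**Figure D5:**
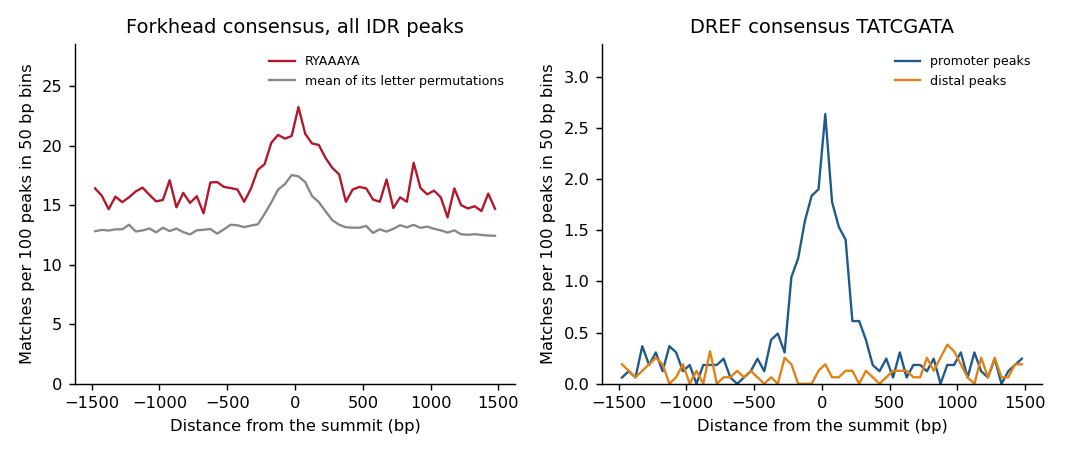
Matches per 100 peaks in 50 bp bins (y axes) by distance from the summit in bp (x axes), on the left for the forkhead consensus and the mean of its 104 letter rearrangements at all IDR peaks, on the right for the DREF consensus at promoter and distal peaks. The forkhead curve and that of its rearrangements both rise at the summit, and the DREF curve rises at promoter peaks.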

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

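The comparisons use peaks on the 6 main arms of dm6. The dm3 lists also hold peaks on heterochromatic and unplaced sequences, which no comparison used. The count there was 257 of 27206 peaks in replicate 3 (0.945%, 95% Wilson interval 0.836 to 1.07), 36 of 30000 in replicate 2 (0.12%) and 46 of 24855 in the pooled list (0.185%), each above the 3 that a count of 0 would allow. That limit only flagged the counts and is no test of them, since the relaxed lists include background. The strongest of the pooled list on these sequences ranked 3775, so the 2872 strongest, which make up the dm3 IDR list, hold none. In replicate 3, 88 were on 3LHet, 79 on 2RHet and 60 on 3RHet, and the strongest ranked 1463 in its list. No explanation of the gap between the replicates was tested.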

How the results depend on the processing

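Flanks matched in A and T content, own promoters, matching on other TSSs and peaks held by both replicates were chosen after seeing the data, and the others before. The overlap of the replicates (63.9% to 75.5% over 5 alternatives) and the promoter excess kept their direction and stayed past the threshold under every alternative run, as did the calls for ribosomal proteins (1.39-fold to 6.25-fold) and for odorant and gustatory receptors over 12 alternatives each. None of the list alternatives merged neighbouring genes without a peak. Spearman's rho between the replicates rose to 0.664 with summits within 50 bp, where 2279 peaks remained. The stronger 50% of the IDR list holds 1601 peaks by construction, and 14 IDR summits lay within 50 kb of slp1 and slp2, a wider region. The number of lists with more peaks fell from 3 to 1 with windows of 20 kb, with neighbours sharing a peak counted once and with a gene's own TSS within 500 bp. The number with fewer was 5 with a TSS within 2 kb and 1 with windows of 20 kb or the stronger 50% of peaks. With own promoters the ratio for Dpp and EGFR signalling was 0.672. Over 216 combinations of list and alternative, 194 kept the call, which counts a list not past the threshold that stayed so. Of 12 alternatives each, the call was kept in 8 for the Notch list and 6 for Dpp and EGFR signalling. It was kept in 7 for blood and fat body markers and 10 for cuticle proteins. Leaving out a replicate left the promoter share at 49.2% to 51.1% and the forkhead difference at 8.59 to 11.6 points, and ended the Dpp and EGFR, the blood and fat body and the Runt calls without replicate 2. Head and eye genes passed as lower without replicate 3, and homeodomain sites as higher without either one of the replicates.

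The number of motifs more frequent at summits was 4, and 7 against uniform random positions, 2 in the stronger 50% and 1 at distal peaks. The forkhead difference stayed past the threshold in 10 of 12 alternatives. It was 0.0312 points against flanks matched in A and T content and -0.343 points against the median of its rearranged letters; both alternatives hold base composition fixed by construction. GAGA factor sites turned to an excess with a 400 bp window (4.15 points), against random positions (1.72) and against matched flanks (1.40), but passed as fewer with a 100 bp window (-0.874) and a flank at 500 bp (-1.69). At distal peaks the DREF difference was -0.636 points and that of M1BP -0.191. The cause of the changes in GAGA factor sites, of the rise in rho and of the changed list and motif calls was not tested. Read depth is unknown, so whether it limits these counts cannot be said. Taking as many of the strongest pooled peaks gave the IDR list itself and so tested nothing.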

Other observations

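The tests in this part of the stricter forkhead form, of peak strength as evidence on other factors, of the slp region and of short words were chosen after the result was seen, and those of gene density and own promoters after the ribosomal protein result but before their own values.

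Short words were sought at the summits beside the 10 motifs. The 10 words of 7 bases most enriched at promoter summits and the 10 most enriched at other summits were chosen on arms 2L, 2R and 4 and tested on 3L, 3R and X, in windows of 150 bp. Of these 20 words, 19 were more frequent at the held-out summits (exact McNemar test, adjusted p below 0.05 within each class), so chance selection does not account for these 19; the exception was TAATGTA (adjusted exact p = 0.177). At promoters the widest held-out difference was that of TTTAAAA, at 18.0% of summits and 6.52% of flanks, followed by TTAAAAA at 20.4% and 9.28%. Summits there are richer in A and T than flanks (62.4% against 55.1%), and base composition was not tested for any of the words. ATCGATA, part of the DREF site already tested, stood at 11.6% and 2.27%. Away from promoters CAGTGTA led by its ratio to the flanks, at 8.04% and 0.893% (9-fold, adjusted exact p = 1.28e-14), followed by CACTGAG at 6.25% and 1.09%. Of the 10 words chosen away from promoters, 6 hold CACTG or CAGTG, which are complementary. These are not limited to such peaks: the promoter word AACACTG holds CACTG (5.73% against 1.48%), and over all promoter peaks CACTGAG stood at 3.68% and 1.53%. The factor that reads this word was not identified.

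The ribosomal protein genes were weighed against 3 explanations. With 1 group, no biological explanation was tested. Gene density does not explain them: against lists matched on window length and on the number of other TSSs, the genes with a peak were 2.48 times the mean. Peaks belonging to neighbours do not explain them either, since summits within 500 bp of the gene's own TSS were 6.25 times the mean of matched lists. What stays open is that these promoters are open in most cells and are precipitated with many factors. At the 68 promoter peaks of this list the forkhead share differed from that in the flanks by -7.35 percentage points (95% interval -22.2 to 7.52), while DREF sites were present at 26.5% of summits and 1.47% of flanks (adjusted exact p = 0.000763). The interval holds 0, which this explanation predicted before the result was seen. It still cannot be told apart from binding of Slp2, because the excess of RYAAAYA lay within that of its rearranged letters, so its lack at these summits decides nothing, a reading made after the value was seen. The stricter form stood at 1.47% of these summits and 7.35% of flanks (adjusted exact p = 0.729), too few matches to decide. Promoters without a peak were not compared, so whether the DREF share here exceeds that of promoters in general was not tested.

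The excess of the forkhead consensus RYAAAYA may come from the base composition of the summits, since 56 of 104 rearrangements of its letters had an excess as large, with a median of 10.7 points. Composition does not account for the whole excess of the stricter GTAAACA, which only 3 of 209 rearrangements reached and which stayed at 1.72 points against flanks matched in A and T content. Away from promoters, however, 40 of 209 rearrangements reached it. Another candidate explanation, that sites of other factors hold most summits, predicts no rise with peak strength, and rho was -0.0097 (-0.0451 to 0.0238). A consensus that follows base composition could give that value too, though A and T content was not examined by peak strength. These explanations of the RYAAAYA excess were therefore not separated, and which forkhead protein binds the stricter sites was not tested.

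The slp1 and slp2 region holds many peaks, 8 in the IDR list and 31 in the pooled relaxed list, the latter more than in 98.7% of windows of the same length. A candidate explanation is an extra copy of the region with the tagged gene, which would raise reads throughout it. The labels do not say whether there is one or how much sequence it holds, and sites bound by Slp2 at its own locus would give the same count.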
